A study of Mus musculus with 6 samples.

How the data were processed

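Gene expression was measured in 6 RNA samples of a mouse fibroblast line with 1-colour Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels' protocols, biotin-labelled cRNA was prepared from total RNA, which was extracted with an RNeasy kit for replicate 1 and with TRIzol for replicate 2. The deposited values are MAS5 signals, per the submitters' processing notes. A MAS5 signal is the brightness of a probe set, the group of short probes that reads 1 transcript, as an intensity on a linear scale. The software version and its settings are not given in the sources used here. The authors' deposited intensities had nearly the same trimmed mean on every array after leaving out 2% of the probe sets at each end, from 150.09 to 150.1, so the arrays had been scaled to a common level. Median signals lay between 49.55 and 52.6, and 40.7% to 42.1% of the probe sets had a signal below 32. The number of arrays, 2 per group, limits the precision of every value.

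The table held 12488 probe sets, of which 66 were Affymetrix controls. Gene names came from the annotation of the array platform, updated through Entrez identifiers, and 0 symbols needed an update. Of the other 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none. Probe sets with several symbols or none were tested but not named. No genome build was named, and no coordinates are given.

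Each array was scaled to the common trimmed mean, with factors between 0.999968 and 1.00006, and the signals were turned into log2(signal + 32). Log2 fold changes are on that scale, which understates the change of dim probe sets. Control probe sets and the lowest 40% of probe sets by mean log2 signal, which lay below a signal of about 29.0, were left out. The remaining 7453 probe sets, of which 6739 named 5662 genes, were tested with limma 3.58.1 in R 4.3.3. The model held 1 mean per group over all 6 arrays, with empirical Bayes moderation and an intensity trend, 3 residual degrees of freedom and 5.23 prior ones. P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. The 3 comparisons were doxycycline withdrawal against doxycycline, estradiol after withdrawal against withdrawal alone, and estradiol after withdrawal against doxycycline.

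There were 21 gene lists, covering pathways, reported target genes and markers of other cell types. The 19 lists with at least 5 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, with the brightest probe set of each gene. Camera asks whether a list stands apart from the other genes. It was repeated with a correlation estimated for each list. The fry test of limma, which asks whether a list's genes moved on balance in one direction, was the other tool. Named genes were drawn from Ccnd1, Irf1, Myc, Hras and Cdkn1a, and the 12 genes with the largest rise and the 12 with the largest fall per comparison (8 and 8 for estradiol after withdrawal against doxycycline) among those that passed the test and moved the same way in both replicate numbers. Where too few passed, places were filled by genes with an unadjusted p under 0.01 and the same direction in both replicate numbers, and these are said not to pass. Up to 4 members of each list, those with the smallest unadjusted p in a comparison, are named too. No probe set carried the symbol Hras.

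The replicate number goes with the extraction method in the labels, so by the labels it marks a shared batch and pairs the arrays. The deviations from the group means, over the tested probe sets, correlated at -0.00727 between the doxycycline and withdrawal groups, at -0.0284 between the doxycycline and estradiol groups and at 0.449 between the withdrawal and estradiol groups. The values with the doxycycline group show hardly any shared shift by replicate number. The value of 0.449 includes the withdrawal and estradiol arrays of replicate 1, which differed at least 2-fold in only 16 probe sets. Fold changes per replicate number are therefore given as descriptions, without evidence of matched pairs. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

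On simulated data for withdrawal against doxycycline, with 7453 probe sets of which 200 were changed and 20 simulations, the test recovered 22.1% of the 2-fold, 95.4% of the 4-fold and 99.8% of the 8-fold changes. Of its calls, 6.66% were false. These rates hold only for the spread and the 200 changes that were simulated. In the data, the gene Cck had a log2 fold change of 2.12 for withdrawal against doxycycline, which is more than 4-fold. Its adjusted p with limma was 0.835. A lack of calls therefore does not show that changes of 4-fold were absent. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The counts of differences between pairs of arrays and the list medians per array were added after the values were seen. The alternatives were the replicate number as a block, the values as deposited, quantile normalization, median centring, an offset of 1 or 100, no filter or a filter of 70%, no intensity trend, only the 4 arrays of the groups compared, the mean of a gene's probe sets in the list tests, the other list tests, and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the others.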

Results

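The data describe a clone of NIH3T3 cells, an immortalised mouse fibroblast line, in which c-Myc and Ha-Ras, a pair of cooperating oncogenes, are held under a Tet-off promoter. Doxycycline keeps that promoter silent and its withdrawal switches the oncogenes on. The cells also carry IRF-1, a transcription factor of the interferon response with growth-suppressing activity, fused to the hormone-binding part of the human estrogen receptor. The fusion is made all the time and becomes active when estradiol is added. RNA was profiled in 3 groups of 2 arrays: a doxycycline group (2 µg/ml, oncogenes off), a withdrawal group (oncogenes on) and an estradiol group (oncogenes on, estradiol for 48 h at 1 mM as the labels give it). The title of the second doxycycline array also names estradiol, while its treatment entry lists doxycycline alone. It was kept in the doxycycline group. The highest signal on an array ranged from 9724 to 15343.

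Across the 6 arrays, similarity followed the group names only in part. The arrays labelled withdrawal replicate 1 and estradiol replicate 1 differed at least 2-fold in 16 of 7453 probe sets, the smallest number for any pair. The arrays labelled estradiol replicates 1 and 2 differed in 250, and the 2 doxycycline arrays in 283. The arrays labelled withdrawal replicates 1 and 2 differed in 920. The array labelled withdrawal replicate 2 differed from the first doxycycline array in 324. Myc, read by 1 probe set, had signals of 62.3 and 49.6 with doxycycline, 25.7 and 118.5 after withdrawal and 31.9 and 28.1 with estradiol. The labels do not say whether this mouse probe set reads the Myc transgene. Irf1, also read by 1 probe set, had signals of 219 and 320 with doxycycline, 212 and 204 after withdrawal and 225 and 155 with estradiol, and passed the test in none of the 3 comparisons.

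**Figure D1:**
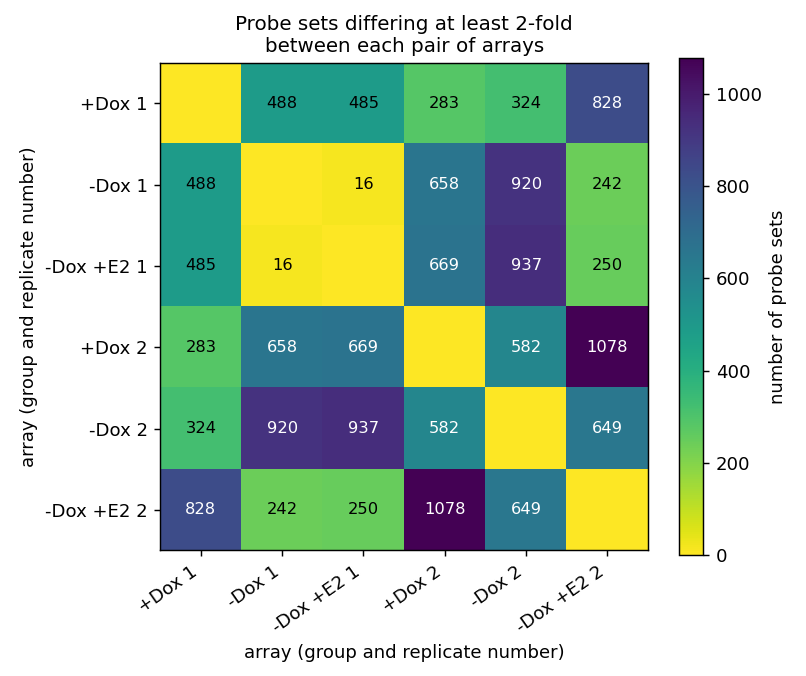
Number of tested probe sets that differed at least 2-fold between each pair of the 6 arrays, with groups written as +Dox (doxycycline), -Dox (withdrawal) and -Dox +E2 (estradiol) and followed by the replicate number. The replicate 1 arrays of withdrawal and estradiol differ in 16 probe sets, and the 2 withdrawal arrays in 920.

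The first comparison set the withdrawal group against the doxycycline group, which asks what the oncogenes change. Doxycycline itself differs between these groups too, so its own effects cannot be told from those of the oncogenes. Cell division genes were higher on average in the withdrawal group, although withdrawal replicate 2 lay below doxycycline replicate 1. Of 33 tested mitosis genes, 32 were higher, with a median log2 fold change of 0.75 (1.03 in replicate 1 and 0.47 in replicate 2). Mki67, the proliferation marker Ki-67, had signals of 244 and 129.8 after withdrawal against 65.0 and 31.3 with doxycycline (log2 fold change 1.43, SE 0.35). Racgap1, which acts in cytokinesis, differed by 1.02 (SE 0.30), and the mitotic kinesins Kif2c and Kif20a by 1.07 (SE 0.36) and 1.34 (SE 0.47). Of 32 DNA replication genes, 31 were higher, with a median of 0.58 (0.72 and 0.34). Without the array labelled withdrawal replicate 1 the medians were 0.20 for mitosis and 0.08 for DNA replication, without withdrawal replicate 2 they were 1.37 and 1.11, and without doxycycline replicate 2 they were 0.46 and 0.24. Relative to the genes' means over all arrays, the median of the mitosis list was -0.53 on withdrawal replicate 2. It was -0.40 on doxycycline replicate 1 and -1.04 on doxycycline replicate 2. For DNA replication these values were -0.54, -0.25 and -0.85. The positive medians in replicate 2 thus rest on the low values of doxycycline replicate 2. The sliding clamp Pcna had signals of 632 and 331 against 251 and 169.6 (1.04, SE 0.38), and the flap endonuclease Fen1 differed by 1.10 (SE 0.37).

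The lists of ribosome biogenesis, glycolysis, heat shock, matrix and chemokine genes had medians closer to 0. Of 35 genes of ribosome biogenesis and reported Myc targets, 31 were higher, with a median of 0.47 (0.77 in replicate 1 and -0.08 in replicate 2, -0.12 without the array labelled withdrawal replicate 1 and 0.86 without withdrawal replicate 2). Srm, the spermidine synthase, had signals of 663 and 253 against 204 and 179 (1.00, SE 0.44), and the nucleolar RNA helicase Ddx21 differed by 0.74 (SE 0.32). Glycolysis genes were higher in 13 of 16 (median 0.37, with 0.85 in replicate 1 and -0.06 in replicate 2), with Pgam1, phosphoglycerate mutase, at 0.87 (SE 0.35). Heat shock genes were higher in 11 of 11 (median 0.27, with 0.65 and 0.17), with the mitochondrial co-chaperonin Hspe1 at 0.71 (SE 0.33). Extracellular matrix genes were lower in 30 of 42 (median -0.17, with -0.60 and 0.02), or 0.02 without withdrawal replicate 1, -0.48 without withdrawal replicate 2 and -0.32 without doxycycline replicate 2, with the metalloproteinase inhibitor Timp2 at -1.08 (SE 0.37). Chemokine and cytokine genes were lower in 11 of 14 (median -0.35, with -0.57 and -0.22), with Cxcl1, a neutrophil attractant, at -0.77 (SE 0.42).

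Camera called these 7 lists in the first comparison, with adjusted p of 5.11e-13 for mitosis, 1.93e-08 for DNA replication, 9.73e-06 for ribosome biogenesis and Myc targets, 0.00778 for glycolysis, 0.00825 for heat shock, 0.0151 for extracellular matrix and 0.00612 for chemokines. With an estimated correlation every one of these calls was lost, with adjusted p = 0.613 with an estimated correlation for extracellular matrix and adjusted p = 0.546 with an estimated correlation for the others. Adjusted over the list alone, 0 members of these lists passed, and 0 passed over all genes. The array labelled withdrawal replicate 1 carried the calls: without it the adjusted p was 0.19 for mitosis, 0.974 for DNA replication, glycolysis and chemokines, 0.65 for ribosome biogenesis and Myc targets, 0.736 for extracellular matrix and 0.512 for heat shock. Without the array labelled doxycycline replicate 1 the adjusted p was 0.286 for glycolysis, 0.123 for heat shock and 0.366 for extracellular matrix, and without doxycycline replicate 2 it was 0.088 for chemokines.

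Single genes did not pass in the first comparison, where the smallest adjusted p was 0.835. Among genes with an unadjusted p under 0.01 and one direction in both replicate numbers, the largest higher value was that of Cck, the neuropeptide cholecystokinin, with signals of 127 and 198 after withdrawal against 19.1 and 6.1 with doxycycline (2.12, SE 0.31). Mki67 came next, followed by Bzw2 at 1.30 (SE 0.31), the phosphatase Ptprv at 1.29 (SE 0.27), the small nuclear ribonucleoprotein pseudogene Snrp1c-ps2 at 1.20 (SE 0.31) and the poly(A)-binding protein Pabpc4 at 1.19 (SE 0.35). Tfdp1, the dimerisation partner of E2F, stood at 1.18 (SE 0.31), Acly, which makes cytosolic acetyl-CoA, at 1.16 (SE 0.28), and the spindle protein Aspm at 1.13 (SE 0.27). Rag1, the lymphocyte recombinase, stood at 1.10 (SE 0.26) and the adaptor Ywhae at 1.02 (SE 0.30). Other probe sets gave -0.26 for Mki67, 0.53 for Ptprv, 0.61 for Pabpc4, and 0.70 and 0.27 for Tfdp1.

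Among lower values of the first comparison, Igsf10 had signals of 161.7 and 372 after withdrawal against 1378 and 626 with doxycycline (-1.78, SE 0.48). Xdh, xanthine dehydrogenase of purine breakdown, had 105 and 165 against 326 and 644 (-1.58, SE 0.40). Lst1 stood at -1.42 (SE 0.36) and the basement membrane protein Nid2 at -1.36 (SE 0.28). Ddit3, the stress-induced factor CHOP, and the thrombospondin Thbs3 both stood at -1.20 (SE 0.32 and 0.28). Ikbke, a kinase of antiviral signalling, stood at -1.16 (SE 0.34), or -0.67 without the array labelled withdrawal replicate 1, and H2-T18, a non-classical MHC class I gene, at -1.10 (SE 0.30). The TGF-beta co-receptor Tgfbr3 stood at -1.04 (SE 0.31), and Chga, chromogranin A, at -0.94 (SE 0.25). The adjusted p was 0.835 for Cck and 0.925 for all the others named here.

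In all, limma called 0 of 7453 probe sets between withdrawal and doxycycline. At an unadjusted p under 0.05 there were 326 (154 higher, 172 lower), against 373 expected by chance. With the replicate number as a block the model also called 0, with 435 at that unadjusted p. At least 2-fold differences in the same direction in both replicate numbers were seen in 25 probe sets (17 higher, 8 lower), and in opposite directions in 62. The fold changes of the 2 replicate numbers correlated at r = -0.0860 across probe sets, which are not independent replicates. Limma called 26 probe sets without the array labelled doxycycline replicate 1, all lower after withdrawal, of which 12 were on the interferon, MHC class I or IRF-1 target lists.

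**Figure D2:**
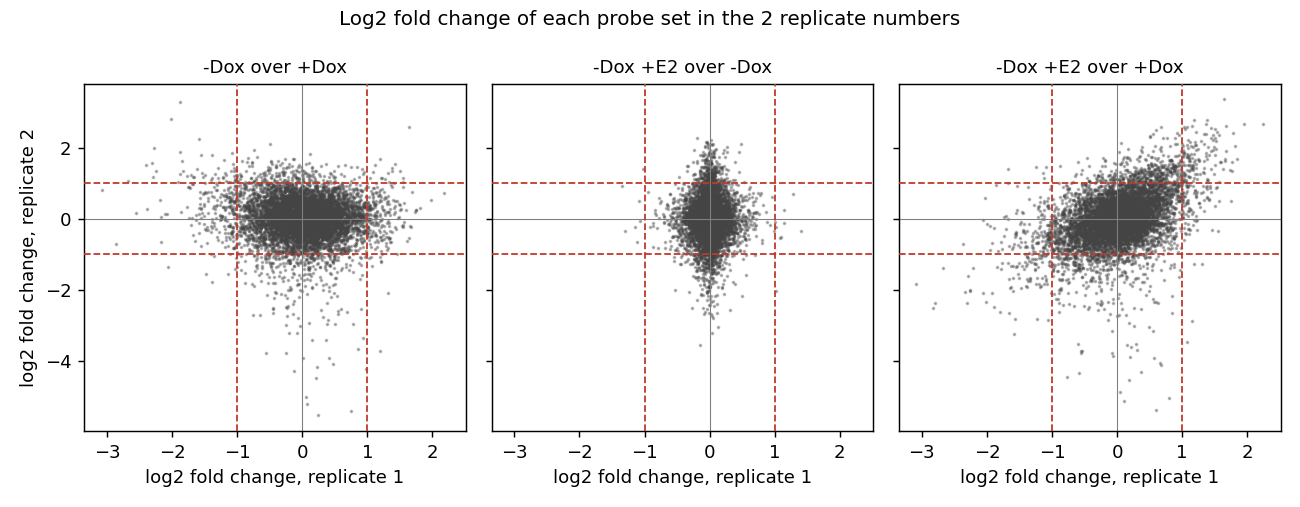
Log2 fold change of each tested probe set in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for withdrawal over doxycycline, estradiol over withdrawal and estradiol over doxycycline, with dashed lines at a 2-fold change. The correlation across probe sets is -0.0860, 0.0112 and 0.454 in that order.

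The second comparison set the estradiol group against the withdrawal group, which asks what IRF-1 activation changes in cells with the oncogenes on. All the cells carry the fusion, so IRF-1 activation cannot be told from other effects of estradiol. The title of the series names cyclin D1 as a gene lowered by IRF-1. Ccnd1, which encodes cyclin D1 and drives entry into S phase, passed the test in neither of its 2 probe sets, with slightly lower values in replicate 1 and higher values in replicate 2. The arrays compared in replicate 1 differed at least 2-fold in 16 probe sets, and the array labelled withdrawal replicate 2 differed from the other withdrawal array in 920. The test therefore cannot decide whether estradiol changed Ccnd1. Its brighter probe set had signals of 333 and 609 with estradiol against 371 and 227 after withdrawal alone, a log2 fold change of 0.58 (SE 0.36, adjusted p = 1.00), with -0.14 in replicate 1 and 1.31 in replicate 2. It was 0.18 without the array labelled estradiol replicate 2, 0.99 without estradiol replicate 1, 0.26 without withdrawal replicate 2 and 0.90 without withdrawal replicate 1. The other probe set had 401 and 186 against 412 and 54.2 (0.65, SE 0.68, adjusted p = 1.00, with -0.03 and 1.34). With doxycycline the signals were 149 and 136 for the brighter probe set and 149 and 128 for the other. Withdrawal against doxycycline gave 0.89 (SE 0.36, adjusted p = 0.925) and 0.20 (SE 0.68, adjusted p = 0.977), which were 0.57 and -0.98 without the array labelled withdrawal replicate 1, and the latter 1.38 without withdrawal replicate 2. Cdkn1a, the cell cycle inhibitor p21, had signals of 1603 and 718 with estradiol against 1519 and 419 after withdrawal in its brighter probe set (0.40, SE 0.58), and 591 and 456 against 640 and 316 in the other (0.19, SE 0.40). These values were -0.49 and -0.29 without the array labelled withdrawal replicate 2, where the other Ccnd1 probe set gave -0.53.

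Lama4, a laminin chain of basement membranes, was the sole gene that met the rule for named genes in the second comparison. Its signals were 9.1 and 11.6 with estradiol against 42.8 and 44.5 after withdrawal alone (-0.84, SE 0.23, adjusted p = 1.00), and it stood at 45.1 and 45.5 with doxycycline. Interferon-stimulated genes were not called by camera, with 12 of 28 higher, a median of -0.05 and an adjusted p of 0.581. Their median was 0.05 in replicate 1 and -0.14 in replicate 2. The MHC class I list (median 0.10) and the reported IRF-1 targets (median -0.10) also had an adjusted p of 0.581. However, the arrays compared in replicate 1 differed at least 2-fold in only 16 probe sets. The order of the labels in replicate 2 is in doubt, as described below. Camera therefore cannot decide here whether estradiol moved these lists. Among the IRF-1 targets, Lox, the collagen cross-linking enzyme, had signals of 1118 and 781 with estradiol against 1153 and 3976 (-1.17, SE 0.56), and the adhesion molecule Vcam1 had 312 and 306 against 323 and 589.5 (-0.46, SE 0.38). For both genes the difference lay almost wholly in replicate 2.

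For 6 other lists the estradiol and withdrawal arrays differed in replicate 2 and hardly in replicate 1. All 32 DNA replication genes were higher, with a median of 0.70 that was 0.04 in replicate 1 and 1.24 in replicate 2. All 33 mitosis genes were higher (0.56, with 0.00 and 1.16), as were all 35 genes of ribosome biogenesis and Myc targets (0.44, with -0.01 and 0.87). Pcna had signals of 698 and 1021 with estradiol against 632 and 331 (0.84, SE 0.38), and the survivin gene Birc5 had 293 and 259 against 205 and 84.2 (0.89, SE 0.38). Extracellular matrix genes were lower in 36 of 42 (-0.44, with -0.00 and -0.84), among them the matrix glycoprotein Tnc at -1.22 (SE 0.51) and the metalloproteinase Mmp14 at -0.97 (SE 0.45). Actin cytoskeleton genes were lower in 20 of 28 (-0.30, with 0.04 and -0.59), with smooth muscle actin Acta2 at -1.33 (SE 0.76), and chemokines in 11 of 14 (-0.39, with 0.01 and -0.92), with the growth factor Tgfb3 at -0.75 (SE 0.32).

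Camera called those 6 lists in the second comparison, with adjusted p of 6.71e-14, 4.95e-12, 2.07e-10 and 9.75e-10 in the order given and 0.000577 for both actin and chemokines. Each had adjusted p = 0.565 with an estimated correlation. Adjusted over the list alone, 0 members passed, and 0 passed over all genes. No list call remained without the array labelled withdrawal replicate 2, where 0 lists were called and the adjusted p was 0.83 for DNA replication, actin and chemokines, 0.945 for mitosis and for ribosome biogenesis, and 0.0646 for extracellular matrix. The medians there were 0.11 for DNA replication, 0.04 for mitosis, -0.02 for ribosome biogenesis and -0.12 for extracellular matrix, and without withdrawal replicate 1 they were 1.12, 1.16, 0.75 and -0.81. Without estradiol replicate 2 the actin list had an adjusted p of 0.0598. Heat shock genes were higher in 10 of 11 (median 0.22, adjusted p = 0.0561), and the list was called with the replicate number as a block (adjusted p = 0.0333), against adjusted p = 0.565 with an estimated correlation.

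Limma called 0 of 7453 probe sets between estradiol and withdrawal, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 52 (25 higher, 27 lower), against 373 expected by chance, and the blocked model called 0 with 64 at that unadjusted p. At least 2-fold differences numbered 16 in replicate 1 and 649 in replicate 2, with 0 in the same direction in both. A difference seen only in replicate 2 also widens the spread between replicates, so the test could hardly call it. The lack of calls therefore does not show that estradiol had no effect. Limma called 17 probe sets (3 higher, 14 lower) without the array labelled withdrawal replicate 1.

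The third comparison set the estradiol group against the doxycycline group. These groups differ in the oncogenes and in estradiol, so the comparison cannot tell an effect of one from an effect of the other. The mitosis, DNA replication and Myc target lists had positive medians in both replicate numbers, while the interferon genes and IRF-1 targets differed in sign between them. Tk1, the thymidine kinase of S phase, had signals of 1078 and 947 with estradiol against 202 and 123 with doxycycline (2.45, SE 0.58). Mki67 had 277 and 355 against 65.0 and 31.3 (2.14, SE 0.35), and the kinetochore gene Pmf1 had 208 and 389 against 44.6 and 9.0 (2.50, SE 0.44). Gtse1, a regulator of G2 phase, stood at 2.31 (SE 0.51), the kinase subunit Cks2 at 2.02 (SE 0.48), gamma-tubulin Tubg1 at 2.00 (SE 0.46), the small nucleolar RNA-binding protein Nhp2 at 2.00 (SE 0.40) and the growth regulator Pa2g4 at 1.99 (SE 0.45). Ccnd1 had a log2 fold change of 1.47 (SE 0.36, adjusted p = 0.255) in its brighter probe set, with 1.01 in replicate 1 and 1.93 in replicate 2, and 0.85 (SE 0.68, adjusted p = 0.606) in the other, which was 0.36 without the array labelled estradiol replicate 1 and 1.35 without estradiol replicate 2.

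Among lower values of the third comparison, none of which passed the test, Igsf10 stood at -2.59 (SE 0.48), Xdh at -2.42 (SE 0.40) and the prostaglandin F receptor Ptgfr at -2.34 (SE 0.53). The collagen-binding proteoglycan decorin, Dcn, had signals of 302.5 and 64.5 with estradiol against 1137 and 560.2 with doxycycline (-2.21, SE 0.62). The chemokine Cxcl5 stood at -2.20 (SE 0.61), the fibroblast growth factor Fgf7 at -2.19 (SE 0.61), the pentraxin Ptx3 at -2.19 (SE 0.47), and Pdgfra, a growth factor receptor of fibroblasts, at -2.18 (SE 0.55) with signals of 617 and 360 against 2587 and 1966. The adjusted p was 0.257 for Dcn and 0.255 for all other genes of the largest changes named in this comparison. Without the array labelled estradiol replicate 2, Dcn was -1.31 and Fgf7 -1.15. For Mki67 the second probe set gave 0.02, and for Pdgfra it gave -1.08.

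**Figure D3:**
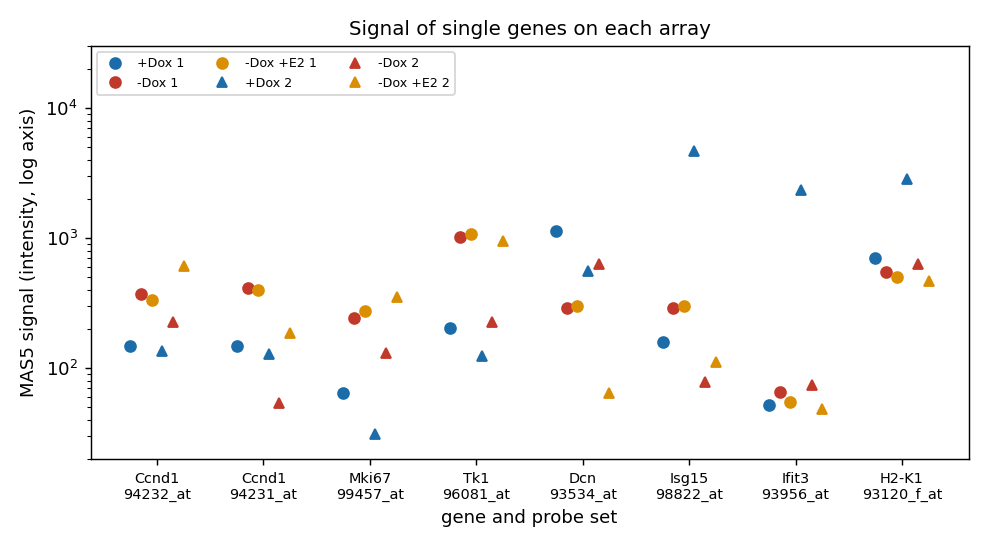
MAS5 signal on a log axis for 8 probe sets, 1 point per array, with colour for the group and circles for replicate 1 and triangles for replicate 2. Mki67 reads 31.3 and 65.0 on the doxycycline arrays and 277 and 355 on the estradiol arrays, and Isg15 reads 4709 on the second doxycycline array against at most 299 on the others.

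By list, 32 of 33 mitosis genes were higher with estradiol than with doxycycline, with a median of 1.42 (1.03 and 1.74 in the 2 replicate numbers). Adjusted over the list alone 25 rose, and 0 passed over all genes. All 32 DNA replication genes were higher (median 1.18, with 0.74 and 1.34, and 0.76 without the array labelled doxycycline replicate 2), and 22 rose when adjusted over the list alone. Of 35 genes of ribosome biogenesis and Myc targets 33 were higher (0.81), and 13 rose when adjusted over the list alone, with Srm at 1.96 (SE 0.44) and the ribosome biogenesis factor Bop1 at 1.64 (SE 0.42). Of 14 chemokine genes 12 were lower (-0.73), and 3 fell when adjusted over the list alone, with the macrophage growth factor Csf1 at -1.26 (SE 0.33) and Cxcl1 at -1.55 (SE 0.42). Extracellular matrix genes were lower in 35 of 42 (-0.54), with Timp2 at -1.65 (SE 0.37) and Mmp14 at -1.80 (SE 0.45). Heat shock genes were higher in 10 of 11 (0.62) and glycolysis genes in 13 of 16 (0.57). Actin cytoskeleton genes were lower in 23 of 28 (-0.41), with Csrp1, a LIM protein of muscle, at -0.98 (SE 0.40). In the matrix, heat shock, glycolysis and actin lists 0 members passed when adjusted over the list alone.

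Camera called these 8 lists in the third comparison, with adjusted p of 1.02e-17 for mitosis, 4.78e-16 for DNA replication, 4.34e-11 for ribosome biogenesis and Myc targets, 8.49e-05 for chemokines, 3.46e-07 for extracellular matrix, 0.00166 for heat shock, 0.00278 for glycolysis and 0.00707 for actin. The calls were lost, with adjusted p = 0.562 with an estimated correlation for actin and adjusted p = 0.488 with an estimated correlation for the others. For actin the adjusted p was 0.18, and for glycolysis 0.0757, without the array labelled doxycycline replicate 1.

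Limma called 0 of 7453 probe sets between estradiol and doxycycline with all 6 arrays in the model. At an unadjusted p under 0.05 there were 1041 (619 higher, 422 lower), against 373 expected by chance, and the blocked model called 0 with 1219 at that unadjusted p. With only the 4 arrays of these groups, 132 probe sets passed (88 rose, 44 fell), of which 22 were on the mitosis or DNA replication lists. Among the calls were 13 of the 16 genes of the largest changes. Those genes had been chosen from the same arrays, so their calls are no separate support. Without the array labelled withdrawal replicate 1 or 2 the counts were 131 and 133, and without doxycycline replicate 1 the count was 28, all lower. At least 2-fold differences in one direction in both replicate numbers were seen in 226 probe sets (135 higher, 91 lower), and in opposite directions in 9.

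Genes of the interferon response separated a single array from the rest. Of 28 interferon-stimulated antiviral genes, 27 had their highest value on the array labelled doxycycline replicate 2, where the list's median lay 2.20 above the genes' means over the 6 arrays. On the other 5 arrays it lay between -0.67 and -0.23. Isg15, a ubiquitin-like antiviral protein, had a signal of 4709 there and 158.8, 288, 299, 79.0 and 111 on the others. Ifit3, which binds in antiviral complexes, had 2339 there and at most 74.1 elsewhere, and Mx2, a dynamin-like antiviral GTPase, had 310.2 there and at most 21.7. Of 13 genes of antigen processing and MHC class I, 12 were highest on that array, with H2-K1 at 2858 against 698 on the first doxycycline array and B2m, the class I light chain, at 5474 against 2363. Of 12 reported IRF-1 targets, 10 of which are also on another list, 10 were highest on it, among them the chemokine Ccl5, with 2028 against at most 12.1 after withdrawal.

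**Figure D4:**
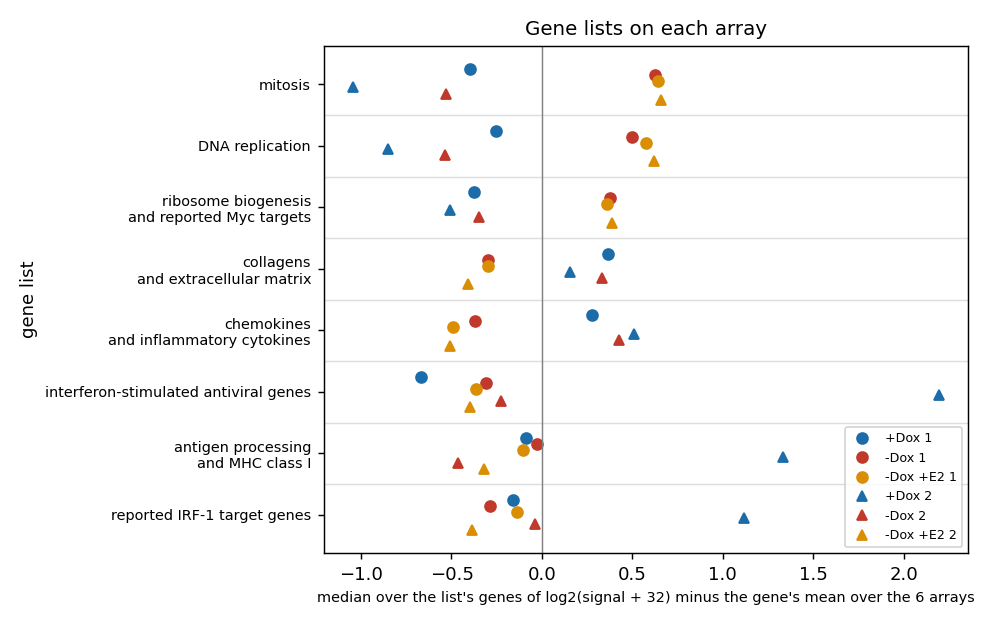
Median over each list's genes of log2(signal + 32) minus the gene's mean over the 6 arrays, 1 point per array, with colour for the group and circles and triangles for replicates 1 and 2. The interferon list stands at 2.20 on the second doxycycline array and between -0.67 and -0.23 on the others, and the mitosis list at -0.53 on the second withdrawal array and 0.62 on the first.

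That array set the comparisons of these lists with doxycycline. After withdrawal 27 of 28 interferon genes were lower (median -1.17, with 0.22 in replicate 1 and -2.58 in replicate 2, adjusted p = 1.93e-08), as were 13 of 13 MHC class I genes (-1.03, adjusted p = 6.38e-08) and 12 of 12 IRF-1 targets (-0.70, adjusted p = 3.34e-05). All had adjusted p = 0.546 with an estimated correlation, and 0 members passed, also when adjusted over the list alone. Without that array the interferon genes were higher after withdrawal (median 0.27, adjusted p = 0.004), the MHC class I genes still lower (adjusted p = 0.0275) and the IRF-1 targets not called (adjusted p = 0.63). With estradiol against doxycycline the medians were -1.15, -0.89 and -0.76, with adjusted p of 5.14e-06, 0.00032 and 0.00032. These became adjusted p = 0.562 with an estimated correlation for the interferon genes and adjusted p = 0.488 with an estimated correlation for the other lists. Without the array labelled doxycycline replicate 1 the interferon medians were -2.47 after withdrawal and -2.59 with estradiol. Again 0 members passed when adjusted over the list alone, and without the array labelled doxycycline replicate 2 the adjusted p was 0.127, 0.299 and 0.525.

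Whether estradiol moved the genes that differed after withdrawal back towards their level with doxycycline was examined across all 7453 probe sets, since the share among called probe sets has no value where 0 were called. Both comparisons contain the withdrawal arrays with opposite sign, which alone gives a negative covariance. The covariance of the log2 fold changes was 0.0271, against a mean of -0.0775 (-0.0875 to -0.0683) in 100 simulations of unchanged groups, a difference of 0.105. Opposite signs were seen in 44.8% of the probe sets, against 66.7% in the simulations. The simulations drew each probe set independently, with the same spread in all groups. They hold no genes that move together. They also lack the wider spread of the withdrawal arrays, which differed at least 2-fold in 920 probe sets, against 283 and 250 within the doxycycline and estradiol groups. The simulated range therefore cannot decide whether estradiol moved genes back. Withdrawal over doxycycline in replicate 1 and estradiol over withdrawal in replicate 2, which share no array, correlated at r = 0.669 across probe sets. The reverse choice gave r = -0.00655. However, the arrays labelled withdrawal replicate 2 and doxycycline replicate 1 differed at least 2-fold in only 324 probe sets, and estradiol replicate 2 and withdrawal replicate 1 in 242. The r of 0.669 thus sets similar pairs of arrays against each other and does not by itself show an effect of estradiol. The reverse choice rests on the estradiol and withdrawal arrays of replicate 1, which differed in 16 probe sets. Without the array labelled withdrawal replicate 1 the difference from the simulated covariance was -0.0262.

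Several lists were called in none of the 3 comparisons with all 6 arrays. In the order of the comparisons, the adjusted p was 0.869, 0.581 and 0.652 for the G1 cyclins, kinases and inhibitors, among them Cdkn1b, the inhibitor p27, at -0.89 (SE 0.30) after withdrawal. It was 0.636, 0.593 and 0.652 for the output of the ERK pathway, in which Plaur, the urokinase receptor, had a log2 fold change of 1.13 (SE 0.25) with estradiol against doxycycline. Adjusted over the list alone, 1 member of each of these lists rose in the third comparison. The adjusted p was 0.259, 0.581 and 0.774 for the unfolded protein and amino acid stress response, where 1 member rose and 3 fell in the third comparison when adjusted over the list alone, with Ddit3 at -1.45 (SE 0.32). It was 0.0997, 0.101 and 0.789 for cholesterol synthesis, 0.636, 0.603 and 0.652 for p53 targets, and 0.247, 0.884 and 0.513 for reported estrogen receptor targets, of which 1 rose in the third comparison when adjusted over the list alone. Without the first doxycycline array, the first comparison called the stress response (adjusted p = 0.0202) and cholesterol synthesis (adjusted p = 0.00599), and without the first withdrawal array cholesterol synthesis (adjusted p = 0.0493). The actin list was called in the first comparison without the array labelled withdrawal replicate 2 (adjusted p = 0.00432, against 0.524 with all arrays), and glycolysis in the second without withdrawal replicate 1 (adjusted p = 0.00727, against 0.101).

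Markers of other cell types showed no call. The adjusted p was 0.928, 0.677 and 0.774 for the 5 tested markers of macrophages and leukocytes, and 0.287, 0.581 and 0.721 for the 5 of adipocytes and muscle. Too few epithelial and endothelial markers were bright enough for a list test. The epithelial cadherin Cdh1 had log2 fold changes of -0.48 (SE 0.28), 0.14 (SE 0.28) and -0.34 (SE 0.28), and the endothelial co-receptor Eng had 0.00, -0.16 and -0.16 (SE 0.24 each). Among the uncalled lists the median, the mean and the direction of camera differed in sign for the leukocyte markers in all 3 comparisons (median 0.01, 0.02 and 0.01, each with camera lower). They also differed for the stress response and the ERK output in both comparisons of the estradiol group, for the estrogen receptor targets against withdrawal and for cholesterol synthesis against doxycycline.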

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

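The tests of explanations in this part were all chosen after the results they bear on were seen. Among 23 mouse control probe sets outside the comparisons, 3 were flagged as bright and at least 2-fold above both doxycycline arrays on both estradiol arrays. These 3 read Tfrc, the transferrin receptor that takes up iron. The lower of the estradiol signals was 396.9, 102.1 and 96.1 for the 3', 5' and middle probe sets, against a highest doxycycline signal of 81.1, 35.7 and 20.6. The array labelled withdrawal replicate 1 read 453.2, 175.4 and 121.7, and withdrawal replicate 2 read 77.2, 4.9 and 16.3. Outside the controls, a Tfrc probe set read 188.2 and 201 with estradiol against 53.8 and 36.8 with doxycycline. The brightest Tfrc probe set differed less, with 1498.7 and 970.6 against 681.8 and 788.7.

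The first pattern is the interferon response on the array labelled doxycycline replicate 2. An exchange of labels with estradiol replicate 2 alone is argued against, because that array differed at least 2-fold from the first doxycycline array in 828 probe sets, against 283 for the array as labelled. RNA from leukocytes is argued against by a median of -0.26 over 7 leukocyte markers, of which 0 were highest there, although only 3 were bright enough to be tested. A general effect of estradiol stays open: the higher of the replicates' medians for estradiol over withdrawal was 0.0508, but that value rests on the withdrawal and estradiol labels, which are in doubt below. It also stays open that the doxycycline culture received estradiol, as its title but not its treatment entry says: the list's median differed by 2.87 between the 2 doxycycline arrays, and an IRF-1 effect in cells with the oncogenes off may be followed up as a hypothesis.

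The next pattern is the near identity of the arrays labelled withdrawal replicate 1 and estradiol replicate 1. Values entered more than once are argued against, since only 24 of 7453 probe sets had identical values. A shared preparation of all replicate 1 arrays stays open: the first doxycycline array differed at least 2-fold from the nearer of the pair in 485 probe sets, but its treatment differed too. The pair itself differed in 16, so a single RNA preparation on both arrays and a culture that did not respond to estradiol cannot be told apart, because both predict that number and no label separates them.

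The last pattern is the low level of proliferation genes on the array labelled withdrawal replicate 2. An effect of the TRIzol batch stays open. The mitosis list lay 0.66 above its mean on estradiol replicate 2, which shares that extraction, and 0.64 above it on estradiol replicate 1, which does not. This goes against an effect on every array, but it rests on labels whose order is in doubt below. On the doxycycline arrays the list was lower with TRIzol, at -1.04 in replicate 2 against -0.40 in replicate 1. Another order of the 3 labels within replicate 2 stays open: the most different pair within a group differed at least 2-fold in 658 probe sets with the doxycycline and withdrawal labels exchanged, and in 669 with all 3 labels moved so that the array with the interferon response is the estradiol array, against 920 as labelled. The other pairs within groups then differed in 324 and 250, and in 324 and 242, against 283 and 250 as labelled. No order left every pair close, and hardly any could. The first withdrawal and estradiol arrays differed in only 16 probe sets, while the replicate 2 arrays differed from each other in 582 to 1078. The counts therefore do not choose between the orders. Oncogenes that were not switched on in that culture, or a wrong label on that array alone, may also explain why it differed from the first doxycycline array in 324 probe sets and from the first withdrawal array in 920, and these possibilities cannot be told apart.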

How the results depend on the processing

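All alternatives here were planned. The replicate number as a block changed no count of called probe sets (0 in each comparison, with a smallest adjusted p of 0.80, 1.00 and 0.201), and its list counts were 10, 7 and 11 against 10, 6 and 11. The list calls depended on the test: 0 lists were called in each comparison with an estimated correlation and 0 with fry, and the cause was not tested. Counts of at least 2-fold differences in both replicate numbers, 25, 0 and 226, were 108, 22 and 433 with an offset of 1, where dim probe sets weigh more. With an offset of 100 they were 6 in the first and 98 in the third comparison, and with the lowest 70% left out 15 in the first. With only its 4 arrays the third comparison called 132 probe sets in place of 0, and leaving out either withdrawal array, which takes the spread between them out of the estimate, did the same. Leaving out 1 array moved the counts to 26 at most in the first comparison (without doxycycline replicate 1), 17 in the second (without withdrawal replicate 1) and 133 in the third (without withdrawal replicate 2). In the first comparison the ranges were -0.60 to 0.78 for Myc, -0.98 to 1.38 for the dimmer Ccnd1 probe set, and -0.55 to 0.40 and -1.61 to 0.17 for the dimmer and brighter Cdkn1a probe sets, between leaving out one withdrawal array and the other. Myc was also -0.00279 with an offset of 1. In the second they were -1.28 to 0.10 for Myc, -0.53 to 1.83 for the dimmer Ccnd1 probe set (0.26 to 0.90 for the brighter), and -0.29 to 0.66 and -0.49 to 1.30 for Cdkn1a between the same arrays. Irf1 ran from -0.36 without estradiol replicate 1 to 0.10 without estradiol replicate 2. In the third, Cdkn1a ran from -0.23 to 0.46 in the dimmer probe set between the doxycycline arrays and from -0.88 to 0.25 in the brighter between the estradiol arrays. Leaving out a withdrawal array gave medians of -0.12 to 0.86 and, in the second comparison, -0.0224 to 0.75 for the Myc target list, and -0.48 to 0.0162 for the matrix list in the first. Leaving out a doxycycline array gave -2.47 to 0.27 and, in the third, -2.59 to 0.15 for the interferon list. The difference of the covariance from its simulated mean ran from -0.0262 without withdrawal replicate 1 to 0.143 without estradiol replicate 1.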

Other observations

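The genes described here were chosen after their values were seen. MHC class II genes, which present antigen to helper T cells and are usually silent in fibroblasts, were read at high levels on the array labelled doxycycline replicate 2. H2-Aa had a signal of 1316.5 there and at most 7.7 on the other 5 arrays, and Cd74, the invariant chain, had 2742.7 against at most 86.0. H2-Eb1 had 293 against at most 59.6, and H2-DMa, which loads peptides, had 845 against at most 209. Ciita, the class II transactivator, had 92.9 against at most 52.8 and lay below the filter on dim probe sets. In all, 92 probe sets were at least 2-fold above all 5 other arrays there, of which 36 were at least 4-fold above. Of the 92, 76 carried a gene name, and 39 of those were on the interferon, MHC class I or IRF-1 target lists. The count was 11 on doxycycline replicate 1, 19 on withdrawal replicate 2 and 11 on estradiol replicate 2. It was 0 on withdrawal replicate 1 and 1 on estradiol replicate 1, which are too alike for either to stand far above the other.

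The array labelled withdrawal replicate 2 had its own high values outside the interferon response. Sox4, a transcription factor of progenitor cells, had signals of 2088.3 and 3871.5 in its 2 probe sets there, against at most 412.4 and 2902 on the other arrays. Acta2, smooth muscle actin, had 842.7 against at most 396.2. The 2 withdrawal arrays lay on opposite sides in the collagen and matrix list, with a median of 0.33 above the genes' means on this array and -0.30 on the first.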
